A study of Homo sapiens with 6 samples.

How the data were processed

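RNA was sequenced from human neuroblastoma cell lines. The 6 libraries were BE2C cells with forced expression of LMO1 (2 libraries), BE2C cells with a vector control (2 libraries), unmodified BE2C cells (1 library) and Kelly cells (1 library). Per the labels' protocols, total RNA was purified on columns and made into paired-end libraries with a stranded total RNA kit, then sequenced on a HiSeq instrument. The same kit is named for all 6 libraries.

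The deposited table holds raw, whole-number counts of reads per gene symbol, with 1 column per library and no normalization. TopHat2 2.0.6, HTSeq and the hg19 build are named in the submitters' processing notes. The gene annotation, the strand setting and any filter were not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes may therefore have been split in a way that cannot be followed. The table had 25370 rows. Of these, 28 carried symbols turned into dates by a spreadsheet, and 2 rows repeated the symbol of an earlier row. Of all rows, 3827 had no read in any library. The reference used here was a later human build than that of the counts, so it served for gene names, transcript lengths, GC content and transcript sequences, and no coordinates are given. In it, 24207 symbols were matched to a gene name.

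Total counts were 18737591 and 22426978 in the LMO1 libraries, 21946052 and 25070942 in the vector libraries, 48663459 in the parental library and 59512958 in the Kelly library. A count of 0 allows up to 3 counts, which is 0.16 CPM (the count scaled to the library total in the usual unit) in the smallest library and 0.0504 CPM in the largest. Exact Poisson intervals (95%) for single libraries cover counting error only, as do these floors, because reads carried no molecular identifiers.

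LMO1 and vector libraries were compared with edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM, genes were kept by filterByExpr (15480 kept, 9890 removed), and a quasi-likelihood F test was followed by Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. Mean CPM values are TMM-scaled over all 6 libraries and are given ± SD. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The common biological coefficient of variation was 3.60%, and the fit had 2 residual degrees of freedom, with 43.7 prior degrees of freedom from sharing across genes. Replicates differed by more than sampling noise (chi-square per degree of freedom 2.91 for LMO1 and 2.75 for vector), against 19.7 to 21.2 between groups, so each library was counted separately.

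Before the data were examined, 34 gene lists were fixed for pathways, cell states, markers of other cell types and technical classes. Each was tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over the 34 lists), with camera at an estimated correlation, and with fry. The genes named were set by a rule fixed at the same time. It takes 11 genes of interest in every comparison, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 1 CPM and no overlap between the groups, and up to 4 called members of each list with the lowest adjusted p. In the single-library comparisons it takes the 10 highest and 10 lowest ratios and up to 3 members of a list. Left out of the top 10s were XIST, Y-linked and HLA genes, annotated pseudogenes, and symbols with the usual prefixes or endings of long non-coding, micro and small RNAs, a pattern that does not remove every non-coding gene. Genes outside the rule are given as chosen after their values were seen. Results of 2 genes under this rule are not reported.

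Kelly was compared with parental BE2C, and parental BE2C with the vector mean, without a test, because 1 side of each had a single library. Log2 ratios of CPM with 1 added were used, over genes with at least 5 CPM on either side. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. To ask where the parental library lay for each called gene, a position was computed on the log2(CPM + 1) scale, with 0 at the vector mean and 1 at the LMO1 mean. This measure shares the vector libraries with the calls, so 100 parental libraries at the vector level were simulated from the fitted dispersion as a reference, which leaves out differences between separately prepared libraries. Positions were also taken with the vector library left out of the fit that called the genes. Intervals of medians and shares over genes treat genes as independent and do not cover the spread between libraries.

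The tests were checked on simulated data with the real means and library sizes. In the LMO1 against vector design with 15299 genes tested, 42 of 65 genes changed 1.5-fold, 52 of 66 changed 2-fold and 63 of 65 changed 4-fold were recovered, with 4 false calls among 15063 unchanged genes. A simulated list of 40 genes shifted by 0.3 on the log2 scale was called, and 0 of 20 unchanged lists were. Genes were drawn independently of each other, so this check cannot show how often correlated lists would be called falsely. Alternatives were DESeq2 1.42.0 size factors and Wald test, upper-quartile and total-count scaling, limma-voom, other low-count filters, a replicate block, all 6 libraries in the fit, removal of small RNA, mitochondrial and histone genes, and each library left out in turn. Similar sequences were searched with blastn 2.17.0, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.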

Results

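The data were gene counts from 6 RNA libraries of human neuroblastoma lines. BE2C and Kelly are neuroblastoma lines with MYCN amplification. LMO1 encodes a LIM-only transcriptional co-regulator, and the study asked how it acts together with MYCN. BE2C cells with forced LMO1 expression (2 libraries) were set against BE2C cells with a vector (2 libraries), and unmodified BE2C cells and Kelly cells gave 1 library each. Depth ran from 18737591 to 59512958 counts per library.

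LMO1 itself was measured in every library. Its level was 6.20 ± 0.489 CPM (SD, n = 2) in the LMO1 libraries and 0.990 ± 0.0907 CPM (n = 2) in the vector libraries. The log2 fold change was 2.65 (SE 0.27, edgeR adjusted p = 3.46e-11). The parental library held 1.93 CPM and the Kelly library 94.1 CPM. By these values LMO1 cells had 3.22-fold more LMO1 RNA than parental cells, and Kelly had 15.2-fold more than LMO1 cells. Both ratios rest on 1 parental and 1 Kelly library, whose content differed from that of the modified libraries, as described below. MYCN, the amplified oncogene of these lines, was at 1597 ± 55.0 CPM with LMO1 and 1658 ± 10.4 CPM with vector. Its log2 fold change was -0.05 (SE 0.0234, edgeR adjusted p = 0.122). Without LMO1 replicate 1, MYCN was called at -0.09 (edgeR adjusted p = 0.00019), and it was also called by limma-voom (limma adjusted p = 0.0182) and without a low-count filter (edgeR adjusted p = 0.017). Over all alternatives the adjusted p for MYCN ran from 0.00019 to 0.577. LMO3, a paralogue of LMO1, had 2 to 6 counts in each of the 4 modified libraries and was not tested, and it reached 25.1 CPM in Kelly.

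**Figure D1:**
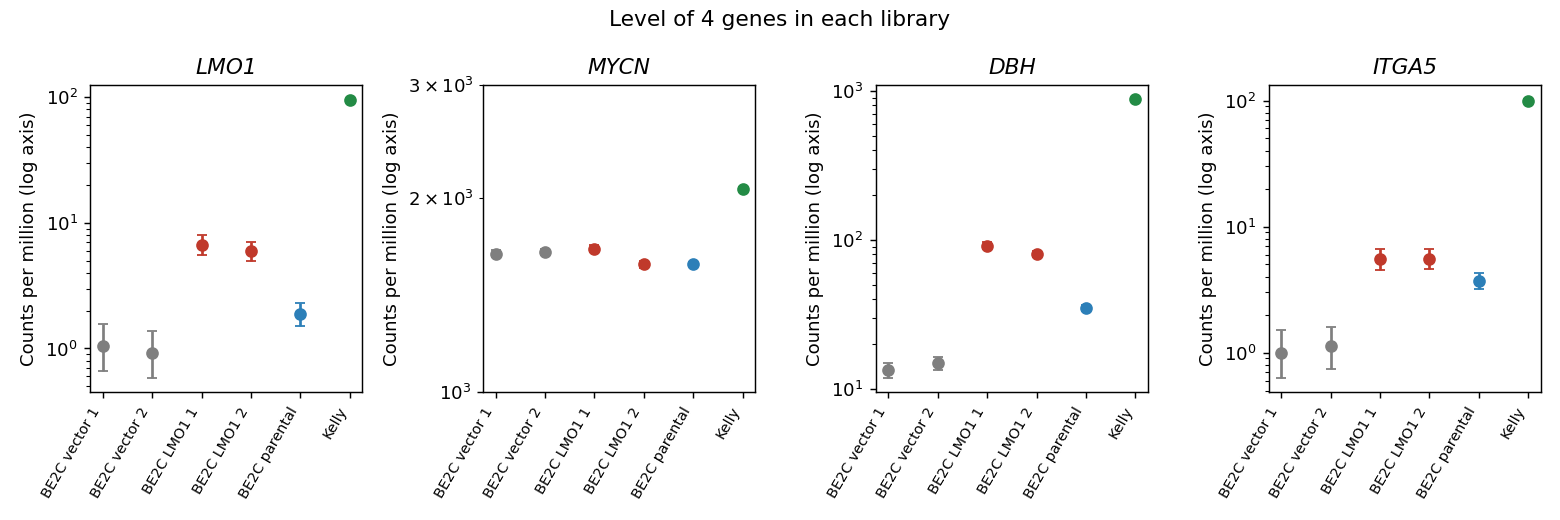
CPM by library total (log axis) of LMO1, MYCN, DBH and ITGA5 in the 6 libraries, with exact 95% Poisson intervals as bars. LMO1 lies at 6.67 and 5.93 CPM in the LMO1 libraries, 1.05 and 0.917 CPM in the vector libraries and 94.2 CPM in Kelly, while MYCN stays between 1580 and 2070 CPM.

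With LMO1, 2463 genes were higher and 2334 lower than with vector among 15480 tested, and most of these differences were small. The median absolute log2 fold change of a called gene was 0.325, and 777 genes changed at least 2-fold, 651 higher and 126 lower. A filter of 5 CPM in 2 libraries left 297 genes of at least 2-fold. Among the genes that rose most were MAGEC2, a cancer-testis antigen (33.5 ± 0.117 against 2.98 ± 0.515 CPM, log2 3.49, SE 0.134), CD200, an immunoglobulin-family membrane protein (log2 3.92, SE 0.205), and ARHGAP36 (log2 4.30, SE 0.233). ZDHHC15, TFAP2C, KCNJ2, FERMT1, FOSB and KIAA1244 completed the top group with MAGEA6. MAGEA6 had 86 counts with LMO1 and 0 with vector, which is at least 32-fold higher against a floor of 3 counts over the vector group, and its reads are uncertain because close paralogues exist.

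NELL2, a secreted neural glycoprotein, fell by 2.49 on the log2 scale (SE 0.0596), from 137 ± 0.838 to 24.3 ± 0.477 CPM (n = 2 each). BMPER, a BMP-binding secreted protein, fell by 2.84 (SE 0.256), and without LMO1 replicate 1 fell by 3.53. EDN1, which encodes the vasoconstrictor endothelin, had 107 counts with vector and 1 with LMO1, a ratio of 95.9 (95% interval 16.8 to 3820). SOST, a secreted WNT antagonist, had 110 counts against 2, a ratio of 49.3 (13.3 to 412). MAGEC1, LRRC32, P2RX3, MYOF, PTGER4 and ZNF208 also were among the 10 lowest.

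**Figure D2:**
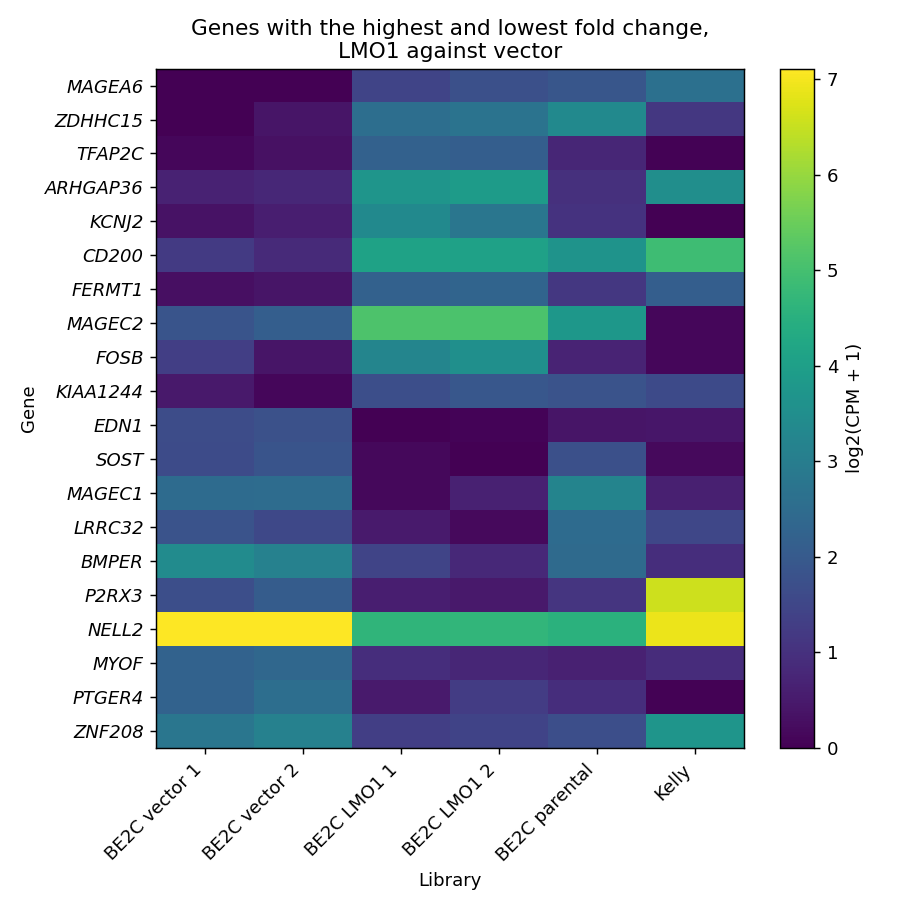
Log2(CPM + 1), as colour, of the 10 genes with the highest and the 10 with the lowest log2 fold change (rows) in each of the 6 libraries (columns). NELL2 is at 137 CPM in vector, 24.3 CPM in LMO1 and 22.1 CPM in parental cells, and MAGEC2 at 33.5 CPM in LMO1 and 2.98 CPM in vector cells.

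Of the 34 gene lists, 14 were called by camera, 9 higher and 5 lower with LMO1. None was called when the correlation between genes was estimated from the data. Camera then uses only the 2 residual degrees of freedom of the fit and has little power. A call missing from that version is therefore not evidence against a list. In that version 7 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.103, while fry, which asks whether a list moves one way and does not compare it with other genes, called 21 lists.

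Genes of hypoxia response and glycolysis rose together. Of 37 tested, 33 were higher and 0 lower, with 36 higher when adjusted over the list alone, and the median log2 fold change was 0.47 (camera adjusted p = 2.45e-43, adjusted p = 0.103 with an estimated correlation). NDRG1, a hypoxia-induced gene, rose by 2.05 (SE 0.0551), and GPI and PGK1, both glycolytic enzymes, rose by 0.46 (SE 0.027) and 0.43 (SE 0.0257). Replication-dependent histone genes rose in 31 of 37 cases, with 0 lower, and equally adjusted over the list alone (camera adjusted p = 6.82e-23, adjusted p = 0.103 with an estimated correlation). HIST1H2BH was at 137 ± 5.70 CPM against 75.8 ± 0.541 CPM. Histone messages lack a poly(A) tail and are read only where a library keeps such RNA, and histone paralogues share sequence.

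Catecholamine and chromaffin genes were higher in 13 of 24 cases and lower in 3, and in 15 and 3 when adjusted over the list alone (camera adjusted p = 4.78e-20, adjusted p = 0.103 with an estimated correlation). DBH, which converts dopamine to noradrenaline, rose by 2.57 (SE 0.0803), from 14.2 ± 1.13 to 84.4 ± 7.69 CPM. TH, the rate-limiting enzyme of catecholamine synthesis, rose by 1.84 (SE 0.249), DDC by 0.70 (SE 0.0335) and the granule gene CHGB by 0.75 (SE 0.0227). Neuronal differentiation genes were higher in 34 of 52 cases and lower in 9, and in 35 and 10 adjusted over the list alone (camera adjusted p = 2.52e-11, adjusted p = 0.114 with an estimated correlation). Among them KIF5C, a kinesin, rose by 1.19 (SE 0.0519), NEFL, a neurofilament, by 0.54 (SE 0.0271), and STMN2 by 0.45 (SE 0.0296).

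Adrenergic neuroblastoma transcription factors moved both ways, with 10 of 29 higher and 11 lower, the same counts as adjusted over the list alone, and the list was not called (camera adjusted p = 0.339, direction down, with a median log2 fold change of -0.05 and a mean of 0.13). LMO1, the forced gene, is itself a member, and without it, left out after the values were seen, 9 of 28 were higher and 11 lower, with a mean of 0.04. SOX11 rose by 3.19 (SE 0.219). TBX2 fell by 0.70 (SE 0.0343), GATA3 by 0.23 (SE 0.0577) and HAND2 by 0.17 (SE 0.0368). Mesenchymal neuroblastoma genes were higher in 15 of 44 cases and lower in 5, with the same counts adjusted over the list alone (camera adjusted p = 0.0135, adjusted p = 0.399 with an estimated correlation). That call was lost without vector replicate 1 (adjusted p = 0.122), without a low-count filter (adjusted p = 0.119) and with all 6 libraries in the fit (adjusted p = 0.205). S100A6 rose by 0.97 (SE 0.029) and CD44, a hyaluronan receptor, by 1.39 (SE 0.177).

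Matrix-modifying enzymes were higher in 22 of 47 cases and lower in 6, and in 24 and 8 adjusted over the list alone (camera adjusted p = 9.83e-07, adjusted p = 0.152 with an estimated correlation). PLOD2 and P4HA1, both collagen hydroxylases, rose by 2.14 (SE 0.149) and 1.13 (SE 0.054), and P4HA1 is also on the hypoxia list. The study named 4 matrix genes, LOXL3, ITGA2B, ITGA3 and ITGA5. The study named them from its own work on LMO1, possibly on these samples, so the list is not independent evidence of its direction. Of the 4, 3 were higher, and all 4 when adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.235 with an estimated correlation). ITGA5 rose by 2.34 (SE 0.275), ITGA3 by 1.20 (SE 0.179) and LOXL3, a lysyl oxidase, by 0.93 (SE 0.121). ITGA2B was at 1.95 ± 0.205 against 1.08 ± 0.0986 CPM (edgeR adjusted p = 0.0695), and was called with all 6 libraries in the fit (edgeR adjusted p = 0.0276, against up to 0.285 over the alternatives). Structural matrix genes went both ways, 17 higher and 11 lower of 53, equally adjusted over the list alone (camera adjusted p = 0.582). VCAN rose by 1.54 (SE 0.0586) and FN1, fibronectin, fell by 1.24 (SE 0.0526). Integrin and focal adhesion genes were higher in 15 and lower in 10 of 46 cases, and in 16 and 10 adjusted over the list alone (camera adjusted p = 0.272).

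Interferon response genes were higher in 13 of 34 cases and lower in 0, and in 14 and 0 adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.209 with an estimated correlation). TAP1, a peptide transporter of antigen presentation, rose by 2.80 (SE 0.259), PARP14 by 1.84 (SE 0.161) and B2M by 0.42 (SE 0.0283). WNT and planar polarity genes were higher in 12 and lower in 3 of 35 cases, and in 13 and 3 adjusted over the list alone (camera adjusted p = 0.0418, adjusted p = 0.488 with an estimated correlation). That call was lost without LMO1 replicate 1, vector replicate 1 or vector replicate 2, with adjusted p = 0.34, 0.12 and 0.0674, and also with limma-voom, without a low-count filter and with all 6 libraries in the fit (0.0715, 0.119 and 0.145). DKK1, a WNT antagonist, rose by 1.08 (SE 0.0551).

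Ribosomal protein genes were lower in 64 of 70 cases and higher in 0, and in 66 and 0 adjusted over the list alone, with a median log2 fold change of -0.22 (camera adjusted p = 5.68e-37, adjusted p = 0.152 with an estimated correlation). RPS20 fell by 0.49 (SE 0.0241) and RPL4 by 0.29 (SE 0.0208). Genes of MYC targets and ribosome biogenesis were lower in 22 and higher in 3 of 51 cases, and in 25 and 5 adjusted over the list alone (camera adjusted p = 0.00176, adjusted p = 0.209 with an estimated correlation), with NPM1 down by a log2 value of -0.29 (SE 0.022). Cholesterol synthesis genes were lower in 15 and higher in 2 of 26 cases, and in 16 and 2 adjusted over the list alone (camera adjusted p = 3.85e-06, adjusted p = 0.152 with an estimated correlation). HMGCS1 fell by 0.58 (SE 0.0375). Small structured RNAs were lower in 7 and higher in 1 of 14 cases, equally adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.587 with an estimated correlation). That call was lost without LMO1 replicate 1 (adjusted p = 0.183) and with all 6 libraries in the fit (adjusted p = 0.13). Fibroblast and endothelial markers were called lower with 6 lower and 5 higher of 17, equally adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.488 with an estimated correlation), and their median of -0.02 changed sign with total-count scaling. Without vector replicate 1 or 2 that call was lost, with adjusted p = 0.236 and 0.118, as it was with limma-voom, without a low-count filter and with all 6 libraries in the fit (0.386, 0.235 and 0.693). ACTA2 fell by 1.89 (SE 0.066) and TAGLN, both smooth muscle markers, by 1.76 (SE 0.141), while DCN rose by 0.84 (SE 0.0897).

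The other 17 lists were not called. Mitosis genes were higher in 6 and lower in 11 of 51 cases, and DNA replication genes in 1 and 6 of 50. Partners of LMO proteins were higher in 4 and lower in 7 of 19 cases, with ID3 down by a log2 value of -0.65 (SE 0.049). Counts of higher and lower genes were 5 and 10 of 27 for p53 targets, 8 and 8 of 31 for TGF-beta and BMP response, 5 and 4 of 26 for Notch, and 4 and 4 of 18 for retinoic acid response. They were 8 and 12 of 30 for cadherins, 13 and 12 of 52 for axon guidance, 9 and 8 of 33 for ER stress, and 7 and 14 of 64 for nuclear oxidative phosphorylation. Immediate early genes gave 9 and 5 of 27, with FOS up by 2.15 (SE 0.102) and FOSB by 3.43 (SE 0.287). The FOSB value was 4.87 without vector replicate 1 and 2.66 without vector replicate 2. Neighbours of MYCN gave 2 and 7 of 22, housekeeping genes 4 and 7 of 15, Schwann and melanocytic markers 4 and 2 of 14, and haematopoietic markers 2 and 0 of 8. The mitochondrial list held 4 tested genes, all MTRNR2L copies that resemble a mitochondrial ribosomal RNA, with 1 higher. Adjusted over the list alone, the counts of higher and lower genes differed for replication (0 and 3), p53 targets (5 and 12), axon guidance (15 and 16), ER stress (10 and 11) and haematopoietic markers (1 and 0), and were equal for the other 12. Camera's direction and the median had opposite signs for cadherins, retinoic acid response, ER stress and Schwann markers. Medians changed sign with the scaling for TGF-beta and BMP response, axon guidance, oxidative phosphorylation and housekeeping genes.

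**Figure D3:**
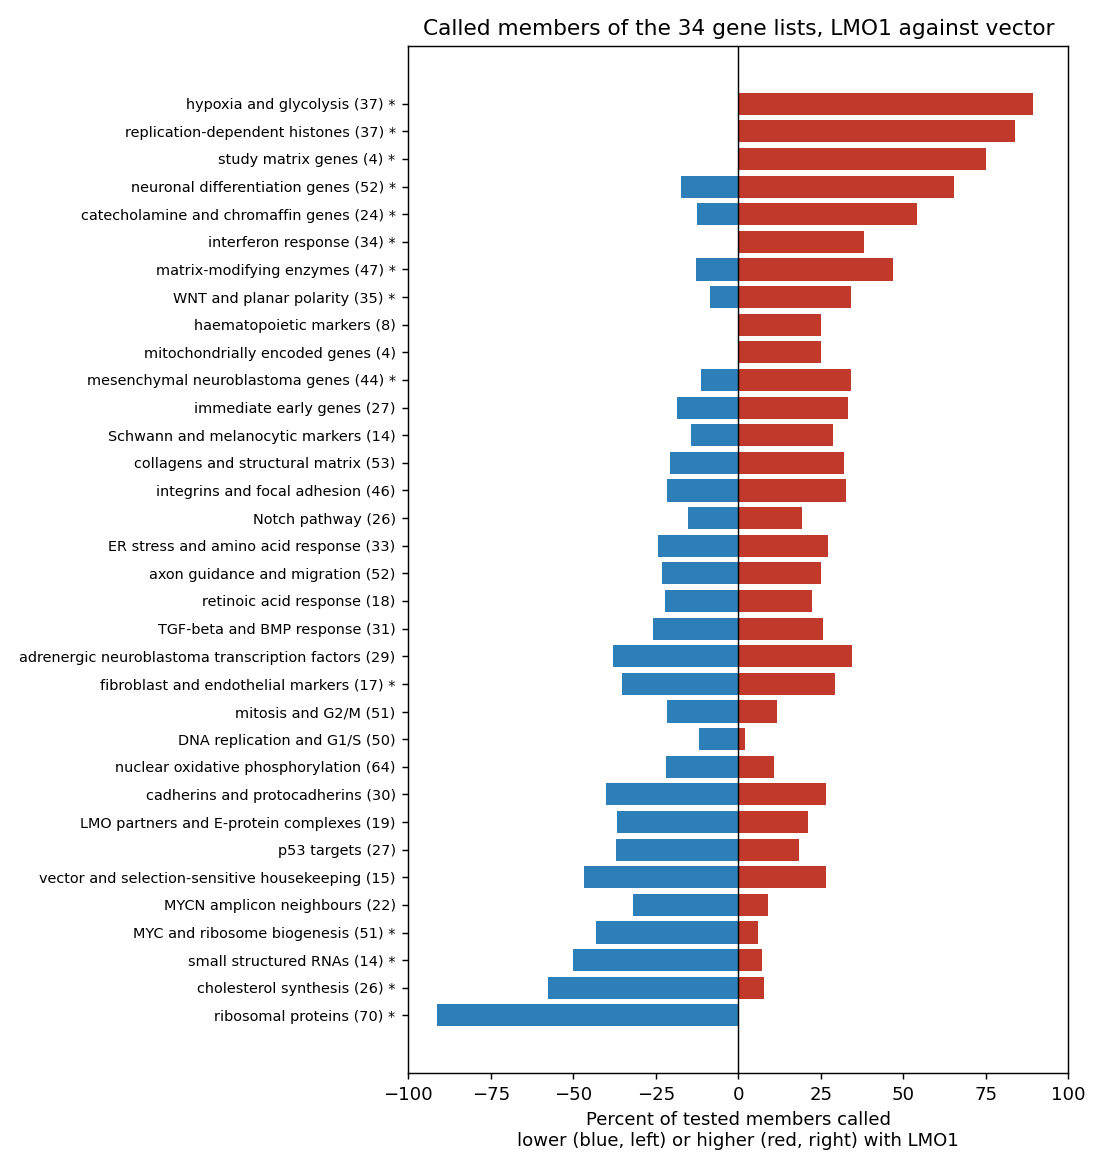
Percent of tested members of each of the 34 gene lists called higher (red, right) or lower (blue, left) with LMO1, with the number tested in parentheses and an asterisk where camera called the list at the preset correlation. Hypoxia and glycolysis genes (33 of 37 higher) and ribosomal proteins (64 of 70 lower) lie at the ends.

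Kelly cells, which express more LMO1, were compared with parental BE2C cells. With 1 library on each side there is no replicate check and no p-value. Of 12387 genes, 1893 were at least 2-fold higher and 1663 at least 2-fold lower in Kelly. Replicates of BE2C differed 2-fold in 1 gene in each group, but parental BE2C and the vector mean, the same line in separate sets of libraries, differed that much in 1037 and 303 of 11727 genes. The catecholamine enzyme TH was at 405 CPM in Kelly and 3.08 CPM in parental cells, and DBH, taken up here after its LMO1 values were seen, at 873 and 35.4 CPM. The catecholamine list as a whole did not follow, with a median log2 ratio of -0.26 at the 12.1 percentile of random lists. The neuronal genes GRIA2 (205 and 0.335 CPM) and SCN1A (167 and 0.314 CPM), the matrix genes NCAN, LAMA1 and FMOD, and MAP7D2, TKTL1, ARMCX2, BMP7 and POTEM had the highest ratios. POTEM is uncertain because of close paralogues. Genes far lower in Kelly were the non-coding RNA MEG3 (2.89 against 1737 CPM), ENPP2, which makes lysophosphatidic acid, RELN, S100A6, S100A11, OPRM1, TSPYL5, GABRA4, IFI16 and TDRD1.

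By list, the 4 study matrix genes had a median log2 ratio of 2.43 in Kelly, higher than 99.6% of matched random lists. Matrix-modifying enzymes had a median of -0.52 in Kelly, at the 0.09 percentile. Hypoxia and glycolysis genes had a median of -0.01 at the 63.8 percentile. Structural matrix genes (0.57), ribosomal proteins (0.49), neighbours of MYCN (0.52), axon guidance (0.45), Notch genes (0.83) and neuronal genes (0.26) lay above 99% of random lists. Mesenchymal genes (-0.67), mitosis genes (-0.64), interferon genes (-1.37), immediate early genes (-1.15) and fibroblast markers (-2.48) lay below all 10000. DNA replication genes (-0.49), nuclear oxidative phosphorylation (-0.39), histones (-1.69) and MTRNR2L genes (-1.82) lay below the 0.2 percentile. MYCN was at 2066 CPM in Kelly and 1612 CPM in parental cells.

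The genes called with LMO1 were then read in the Kelly to parental ratio. Those higher with LMO1 had a median of -0.06, at the 45.3 percentile of random lists, and those lower had a median of -0.22, below all 10000. Restricted to 2-fold calls, the higher genes had a median of 0.12, above all 10000 random lists, although its 95% interval ran from -0.01 to 0.24. The lower genes of at least 2-fold had a median of -0.22 at the 5.13 percentile, so their place below all random lists was not kept under this restriction. Of called genes, 54.6% had the same sign in both differences (95% interval 53.2 to 56.0, which treats genes as independent), against 49.9% by chance. By direction, 1174 of 2463 higher genes and 1446 of 2334 lower genes had the same sign. Across all genes tested, Pearson's r was 0.108 and Spearman's rho 0.0882, and genes are not independent replicates.

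Parental BE2C cells were set against the vector mean to place the control. Of 11727 genes, 1037 were at least 2-fold higher and 303 at least 2-fold lower in the parental library. Without histone and small RNA families, an alternative added after the data were seen, 162 were lower. This group, taken by symbol, also held micro RNA and MTRNR2L genes. Histone genes (median log2 ratio -5.90, 35 of 35 at least 2-fold lower) and small structured RNAs (-6.98) had the lowest medians. The group with micro RNA and MTRNR2L genes made up 4.78% to 5.16% of counts in the 4 modified libraries, 0.358% in the parental and 0.154% in the Kelly library. Histone genes alone made up 1.01% to 1.23%, 0.0423% and 0.0138%. PLCG2, a phospholipase, was at 4829.8 CPM in vector, 5520.1 CPM in LMO1, 1.47 CPM in parental and 0.738 CPM in Kelly cells. Hypoxia genes had a median of 0.76 and neuronal genes of 0.41, above all 10000 random lists. The 4 MTRNR2L genes of the mitochondrial list had the highest median, 3.91, with 4 of 4 at least 2-fold higher. Axon guidance genes (0.45) lay above 99.9% of random lists, while ribosomal proteins (-0.49) and cholesterol genes (-0.35) lay below all, as did nuclear oxidative phosphorylation (-0.44), and mitosis genes (-0.18) lay at the 0.02 percentile. Hypoxia, neuronal, ribosomal protein and cholesterol genes thus differed from vector in the same direction as with LMO1, so the vector libraries may stand apart for these lists. Catecholamine genes (-0.08) and histone genes did not follow their direction with LMO1. All of these stand beside the difference in library content.

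**Figure D4:**
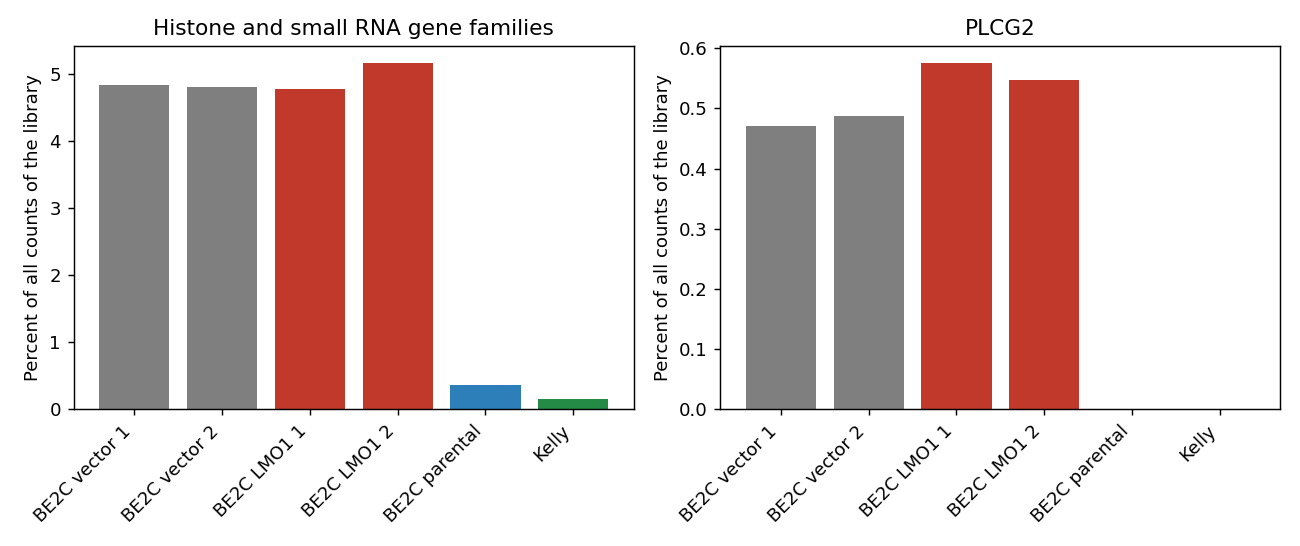
Percent of each library's counts (bars from 0) in histone and small RNA gene families, with micro RNA and MTRNR2L genes, left, and in PLCG2, right. The families take 4.78% to 5.16% in the 4 modified libraries, 0.358% in parental and 0.154% in Kelly cells, and the PLCG2 bars for parental and Kelly are too low to be seen.

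For genes called with LMO1, the parental library lay nearer to vector for 42.2% of the higher genes (1040 of 2463) and 48.1% of the lower ones (1122 of 2334). With 2-fold calls these shares were 42.2% and 34.9%, and with 2-fold calls of at least 5 CPM, a limit added after the data were seen, 31.6% of 196 and 43.8% of 32 genes (95% interval 26.4 to 62.3 for the latter). The vector libraries enter both the calls and this measure, so an even split is not the value for no change. A parental library simulated at the vector level gave 98.1% and 96.6% over all calls, with the spread between replicates alone and not that between separately prepared libraries. CD200 was at 11.5 CPM and ZDHHC15 at 9.44 CPM in the parental library, nearer to the LMO1 than to the vector level, while TFAP2C (0.712 CPM) and ARHGAP36 (0.963 CPM) were nearer to vector.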

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

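Alternatives were planned before the data were examined, except the removal of histone and small RNA families in the single-library comparisons and a 5 CPM limit on the called genes placed in the parental library. With all 4 libraries, calls of LMO1 against vector ranged from 3546 (DESeq2 Wald test) to 4847, the latter with a replicate block. The replicate numbers did not pair the libraries (correlation of deviations -0.0209), and the block gave 2473 higher and 2374 lower genes. With 1 library left out, 3493 to 3636 genes were called, 592 to 681 of them at least 2-fold, and the lone library of a group was then assumed to vary like the others. No gene called in the main fit was called in the opposite direction in any of these fits. Total-count scaling moved the split to 2735 higher and 1853 lower. Of 2050 values of single named genes, 2027 kept their direction and side of the threshold, 19 fell short of it, 4 passed it and 0 reversed. The count of 2-fold genes fell from 777 to 297 with at least 5 CPM in 2 libraries, a filter that tests fewer genes. No gene list was called (0 of 34) with an estimated correlation. For hypoxia (-0.00737), catecholamine (-0.0402), histone (-0.0194) and neuronal genes (-0.00812) the estimate lay below the preset 0.01. A correlation above the preset was therefore not why these calls were lost. Other called lists, such as ribosomal proteins (0.105), had estimates above it. With an estimated correlation, camera also refers its statistic to the residual degrees of freedom of the fit, here 2. It therefore had little power to call any list with 2 libraries per group. How much of the loss came from each source was not tested. For Kelly against parental, genes at least 2-fold higher were 1162 with a limit of 20 CPM, which compares fewer genes. For parental against vector, genes at least 2-fold lower were 189 with a pseudocount of 5, 169 with a limit of 20 CPM and 162 without histone and small RNA families. In the Kelly to parental ratio, the median of genes higher with LMO1 turned from -0.06 to 0.115 when only 2-fold calls were used, and that of lower genes was -0.188 with a pseudocount of 5. The share of higher genes whose parental value was nearer to vector was 44.7% with library totals and 45.4% with DESeq2 size factors. For lower genes it was 45.4%, 44.6% and, with 2-fold calls only, 34.9%. The cause of these shifts was not tested. Depth limits genes such as MAGEA6, EDN1 and SOST, whose lower group had 0 to 2 counts.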

Other observations

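Of the tests in this part, only that of transcript length and GC content was set before its result was seen, and all others were chosen after seeing the values they use. Further gene families were grouped by symbol after the data were seen, 12 in all, and tested with camera over those 12. S100 genes, which encode small calcium-binding proteins, were higher with LMO1 in 5 of 12 cases and lower in 0 (adjusted p = 0.000114, adjusted p = 0.361 with an estimated correlation). Besides S100A6, S100A16 rose by 1.33 and S100A4 by 0.36. Proteasome subunits were lower in 14 of 36 cases (adjusted p = 0.00452, adjusted p = 0.361 with an estimated correlation). The single higher subunit was PSMB8, an interferon-induced immunoproteasome gene, at 5.53 CPM with LMO1 and 0.686 CPM with vector, and PSMB1 fell by 0.34. Neither median changed sign under 4 scalings.

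The other 10 families were not called. Aminoacyl-tRNA synthetases were lower in 10 of 18 cases and higher in 1 (adjusted p = 0.0508), where the higher gene was WARS at 0.29. Genes named ZNF were lower in 77 and higher in 30 of 476 cases (adjusted p = 0.0915), and RGS genes higher in 4 and lower in 3 of 14. MAGE and related cancer-testis genes were higher in 5 and lower in 2 of 9 cases (adjusted p = 0.0795). MAGEC2, MAGEA6, MAGEA4 and PAGE5 were among the higher ones, MAGEC1 and MAGED2 the lower ones, and reads of close paralogues make single members uncertain. Genes named GPR gave 11 higher and 2 lower of 51, solute carriers 53 and 33 of 243 (with a median that changed sign between scalings), and potassium channels 11 and 10 of 57. GABA and glutamate receptor subunits gave 8 and 8 of 31, tubulins 4 and 3 of 16, and chaperonin and HSP genes 6 and 9 of 28.

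The first pattern is that the parental library lay nearer to LMO1 than to vector for most 2-fold genes, with a median position of 0.619 for higher and 0.758 for lower genes (0 is vector, 1 is LMO1), though the 32 lower genes of at least 5 CPM left a wide interval (0.104 to 1.07). Counting noise shared through the vector libraries was argued against. Genes called at 2-fold in a fit with 1 vector library were placed with the other, which that fit did not hold. Their median positions were at least 0.601, with every lower 95% bound at 0.501 or above. These bounds treat genes as independent, although all genes were read in the same parental library. A difference in preparation or batch stays open. The Kelly library, which like the parental one held few histone and small RNA reads, had median positions of 0.777 and 1, but it is another line. Technical classes went both ways. Histone genes, low in both libraries, were higher and not lower with LMO1 (median 0.26), opposite to what a shared loss of such RNA would give. Small structured RNAs, lower in the parental library (-6.98), were also lower with LMO1 (median -0.12, 7 of 14 lower). MTRNR2L genes, higher in the parental library (3.91), had a median of 0.23 with LMO1, with 1 of 4 called. Movement of the vector line away from the parental line also stays open, with 27.8% of the genes within 0.25 of the LMO1 level and 18.1% within 0.25 of vector. These cannot be told apart with 1 parental library, and an effect of LMO1 cannot be separated from a property of the vector line for these genes.

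The second pattern is the high PLCG2 count in the 4 modified libraries. One annotated PLCG2 transcript holds a stretch of 239 bases with 97.9% identity to the 7SK RNA, an abundant nuclear RNA without a poly(A) tail, so reads of 7SK may have been counted in PLCG2. Loss of RNA without poly(A) from the parental and Kelly libraries fits the histone median of -5.90. The 5 other genes with a 7SK-like stretch, of lower identity (90.3% to 91.6%), do not settle this: in the modified against the other libraries ZNF277 was at 30.6 and 20.8 CPM, RIMBP3 at 0.626 and 0.207 CPM and KCTD19 at 0.396 and 2.48 CPM, and 2 had no reads. Expression of PLCG2 itself, at a log2 difference of -10.94 between parental and vector, cannot be excluded without the place of the reads within the gene.

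The third pattern is the rise of hypoxia genes with the fall of ribosomal protein genes. A trend in transcript length and GC content was then removed. The hypoxia median was 0.49 (95% interval 0.35 to 0.63, 36 of 37 genes). The ribosomal protein median was -0.222 (-0.24 to -0.19, 70 genes). Both intervals treat genes as independent and do not cover the spread between libraries or cultures. The medians that remained argue against such a trend, so measured, as the whole cause. Length and GC were those of the longest annotated transcript of each symbol, which may not be the transcript counted, so a length effect is not fully excluded. TMM scaling was argued against as well, since over 4 scalings the ribosomal median was at most -0.19 and the hypoxia median at least 0.47, while the median of all genes moved by at most 0.03. Both lists differed in the same direction between the parental and vector libraries, with medians of 0.761 and -0.49, so the vector libraries may stand apart from the other BE2C libraries. The state of the cultures at harvest, such as density or age of the medium, also stays open, as does an effect of LMO1, although Kelly against parental cells, a difference between lines, had medians of -0.01 and 0.49, and these cannot be told apart with 1 parental library and labels that do not describe the cultures.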
